A study of Mus musculus with 9 samples.

How the data were processed

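Small RNA libraries of subcutaneous adipose tissue were made from 9 mice, 3 in each of the groups WT, Hete_KO and Homo_KO. Per the labels' protocols, RNA was extracted with Trizol and libraries were prepared with Illumina's TruSeq small RNA kit, and per the submitters' processing notes the genome build was mm10. The aligner, the counting tool, the miRNA annotation and the normalization are not given in the sources used here. The series' design text says that each replicate came from an individual mouse. Groups were taken from the genotype label of each sample.

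The deposited files hold 1 value per mature miRNA on a log2 scale. Their name speaks of FPKM, but the values are not linear: they run from 0 to 20.0, and the highest value is the same in all 9 libraries. The lowest distinct levels are those that a mean over 9 libraries of log2(whole number + 1) would give. Of 21 distinct levels under 2.3, 18 gave a whole number within 0.05 when 2 was raised to 9 times the level, where chance gives 10%. The authors' values were therefore treated as quantile-normalized log2(x + 1) values. Quantile normalization gives every library the same set of ranked values, so that differences in total miRNA content or depth cannot be seen, changes of the most abundant miRNAs are steps between shared rank levels, and a large rise of muscle miRNAs pushes other miRNAs down in rank. Back-transformed values sum to between 6681250 and 6681290 in each library for this reason. The number of reads is unknown, and no counting interval is given. The only trace of depth is the number of miRNAs at a library's lowest value, from 63 to 152.

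The test planned before the data were examined took log2(value + pseudocount). Because the values were already logarithms with 1 added, no pseudocount was added, and the planned filter was applied on that scale: a miRNA was tested if it lay above the library's lowest value in at least 3 libraries and its mean was at least 3.46, which is log2(10 + 1). This kept 489 of 860 miRNAs and left out 371. Among the tested miRNAs 12, in 5 sets, had values identical to those of another in every library. Group means were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a variance trend), with all 9 libraries in the fit and no covariate, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are on the log2(x + 1) scale, which understates those of rare miRNAs. A moderated F-test compared the 3 genotypes. Values per library come with the SD over 3 mice, and single measures were compared by exact permutation tests. Comparison of the knockouts together against WT was added after the data were seen, as was the simulation of miRNAs selected in Homo_KO.

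Before the data were examined 16 miRNA lists were fixed: endothelial miR-126, endothelium and angiogenesis, miR-17-92 and paralogous clusters, miRNAs reported to promote and to inhibit brown or beige adipocytes, adipogenesis and obesity, the let-7 and miR-30 families, the imprinted Dlk1-Dio3 cluster, and markers of skeletal muscle, leukocytes, erythroid cells, epithelium and mammary gland, fibroblast and mural cells, neural tissue and liver. The lists overlap. Those with at least 3 tested members (15 of them) were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. No list call held with an estimated correlation. The rule for naming miRNAs was also fixed then: for each comparison, the 12 called miRNAs with the largest absolute change; where fewer than 6 passed, also the 5 higher and 5 lower with the smallest p, as values; the 2 most abundant members of each list; the 10 most abundant miRNAs; and miR-126a-3p and miR-210-3p.

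Hairpin coordinates and host genes come from the GENCODE vM21 annotation of GRCm38, the assembly that mm10 names, in which 844 of the 860 miRNAs matched a hairpin gene by name. The steps were tested on simulated data with the spread within the 3 genotypes, drawn independently for each miRNA. With 200 of 489 miRNAs changed in Homo_KO, 36.5% of log2 changes of 0.5 were recovered, 74.0% of changes of 1 and 95.5% of changes of 2. Of the calls, 3.17% were false. A list shifted by 0.5 was found in 20 of 20 runs. Members of real lists are correlated (estimated at 0.405 for the Dlk1-Dio3 cluster), so these rates need not hold for the list calls. Alternatives were another pseudocount, no filter and a stricter one, scaling by the median, a repeated quantile normalization, no variance trend, sample weights, the replicate number as a block, only the groups compared, and each library left out in turn. Added after the data were seen were the mean of miR-1a-3p, miR-133a-3p, miR-133b-3p and miR-206-3p as a covariate, leaving out the 3 libraries where that mean was highest (Hete_KO replicate 2 and WT replicates 1 and 2), and the number of miRNAs at the lowest value as a covariate. Count-based tests were not run, since no counts could be recovered. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.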

Results

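Small RNA was sequenced from subcutaneous adipose tissue, the fat under the skin, of mice in which Ago1 was knocked out in endothelial cells and of wild-type littermates. Ago1 encodes an Argonaute protein, which binds mature miRNAs and carries them to their target mRNAs. All animals were 24 weeks old and had eaten a diet high in fat and sucrose for 16 weeks from the age of 8 weeks. There were 9 libraries, each from an individual mouse: 3 labelled WT, 3 labelled Hete_KO and 3 labelled Homo_KO. Each library gave a value for the same 860 mature miRNAs on a quantile-normalized log2 scale, so that the summed abundance was nearly the same in every library by construction and the number of reads per library is unknown. A sign of depth that remained was the number of miRNAs at a library's lowest value, which was 79 ± 21.9 in WT, 119 ± 28.4 in Hete_KO and 120 ± 19.8 in Homo_KO (mean ± SD, n = 3 mice each). For Homo_KO against WT an exact permutation test of these counts gave a two-sided p of 0.2, where 3 mice against 3 cannot give less than 0.1, so that a difference is left open. Pairs of libraries of the same genotype had Pearson correlations of 0.966 to 0.983 across miRNAs, and pairs of different genotypes 0.962 to 0.984. The files list mature miRNAs only, so Ago1 itself was not analysed here and the genotype labels were taken as given.

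The adipose libraries were dominated by a few miRNAs, and the 10 most abundant held 67.4% of the summed abundance. miR-143-3p, which is abundant in smooth muscle and stromal cells, had the highest mean over the 9 libraries (log2 19.87), followed by let-7a-5p (19.44), let-7f-5p (18.89) and let-7c-5p (18.74). The others were miR-30a-5p (18.33), miR-21a-5p (18.30), miR-26a-5p (18.17), miR-30d-5p (18.03), let-7b-5p (18.03) and miR-30e-5p (17.72). None of these 10 passed the test in any comparison of a pair of genotypes. Their values are positions in a shared ranking, and several libraries hold the identical value: miR-30e-5p was at 17.83 in all 6 knockout libraries and at 17.49 ± 0.08 in WT (SD, n = 3). Endothelial miR-126a-3p was almost as abundant, at 17.80 ± 0.21 in WT, 17.29 ± 0.40 in Hete_KO and 17.53 ± 0.08 in Homo_KO (SD, n = 3 each).

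miRNAs of other tissues varied between libraries of the same genotype. The skeletal muscle miRNA miR-1a-3p was at 18.47, 18.99 and 12.09 in WT replicates 1, 2 and 3, at 14.84, 19.993 and 14.16 in Hete_KO and at 16.17, 11.43 and 11.98 in Homo_KO, and miR-133a-3p, another muscle miRNA, moved with it. The mean of 4 muscle miRNAs was 11.56 ± 3.47 in WT, 11.05 ± 2.93 in Hete_KO and 8.42 ± 2.89 in Homo_KO (SD, n = 3 each), with a two-sided p of 0.2 for Homo_KO against WT (exact permutation test, smallest possible 0.1), which leaves a difference open. The liver miRNA miR-122-5p was at 7.48 in WT replicate 1 and between 11.71 and 14.98 in the other 8 libraries. The mean of the epithelial miRNAs was 8.25 in Hete_KO replicate 1 and between 4.06 and 5.96 elsewhere.

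**Figure D1:**
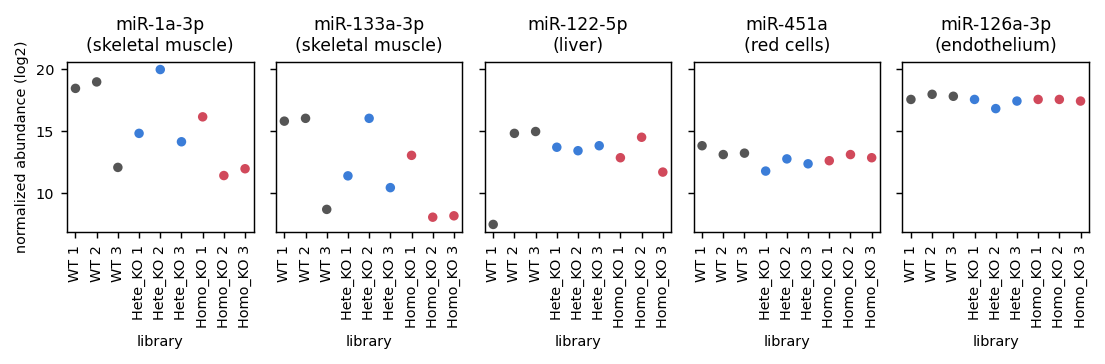
Normalized abundance (log2, vertical axis) of 5 miRNAs typical of skeletal muscle, liver, red blood cells and endothelium in each of the 9 libraries (horizontal axis), coloured by genotype as WT grey, Hete_KO blue and Homo_KO red. miR-1a-3p runs from 11.43 to 19.993, while miR-126a-3p has group means between 17.29 and 17.80.

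The comparison of Homo_KO with WT asks which adipose miRNAs differ when both are fed the same diet. Of 489 miRNAs tested, 8 were higher and 8 lower in Homo_KO (limma, Benjamini-Hochberg adjusted p under 0.05). The highest rises were those of miR-129-1-3p and miR-129-2-3p, with log2 fold changes of 3.11 ± 0.67 (SE, adjusted p = 0.0409) and 2.82 ± 0.54 (adjusted p = 0.0314). They come from the hairpins Mir129-1 (GRCm38 chromosome 6, 29022619 to 29022691, in an exon of the long noncoding RNA gene Gm3294) and Mir129-2 (chromosome 2, 94241364 to 94241453, in an intron of Mir670hg), and their nearly identical sequences can share reads, so these are not independent. miR-215-5p, a miRNA of the p53-responsive miR-192 family, rose 3.78-fold, from 3.25 ± 0.17 in WT to 5.17 ± 0.15 (SD, n = 3 each, adjusted p = 0.00942). Its WT mean lay under the filter's level of 3.46, so it was tested through its values in the knockouts. miR-3964 rose 3.52-fold, from 6.08 ± 0.06 to 7.89 ± 0.24 (adjusted p = 0.00552). miR-142a-5p, of blood cells, rose by 1.26 ± 0.25 on the log2 scale, miR-3970 by 1.02 ± 0.18 and miR-203-3p, of epithelia, by 0.95 ± 0.18 (SE). The more abundant arm of the same hairpin, miR-142a-3p, was not called, with means of 12.12 in WT and 12.34 in Homo_KO. That arm was named after its values were seen.

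Among the miRNAs lower in Homo_KO, miR-342-5p (Mir342, chromosome 12, 108658620 to 108658718, in an intron of Evl) had a log2 fold change of -1.64 ± 0.29 (SE, adjusted p = 0.0283). miR-351-5p, from an X-linked cluster (Mir351, 53053255 to 53053353), fell from 9.74 ± 0.11 in WT to 8.61 ± 0.07 (SD, n = 3 each), a log2 fold change of -1.13 ± 0.14 (SE, adjusted p = 0.00552). Both arms of miR-221 (Mir221, chromosome X, 19146294 to 19146388), a miRNA of endothelium and of proliferating cells, were lower, the 3p arm by -0.96 ± 0.21 and the 5p arm by -0.95 ± 0.19. miR-139-3p, which lies in an intron of Pde2a, changed by -0.96 ± 0.19. The remaining called miRNAs are outside the rule for naming and were named after their values were seen: miR-154-5p (-0.87), miR-503-5p (-0.79), miR-18a-5p (-0.71) and miR-1843a-5p (0.66).

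Of the 16, only miR-215-5p was also called in Hete_KO against WT. All 16 had the same sign there, with a median ratio of Hete_KO to Homo_KO log2 fold changes of 0.819. Because the WT mice are shared and the 16 were selected in Homo_KO, this alone does not show a change in Hete_KO. Of 100 simulations of unchanged groups, 52 gave the same sign for all of the 16 miRNAs with the smallest p. A ratio as high came in 20 of them (mean ratio 0.462). Homo_KO was unchanged in these simulations too, so they do not cover a change in Homo_KO alone. At an unadjusted p under 0.05 there were 66 higher and 51 lower miRNAs, and in 160 of the 489 (32.7%) the 3 Homo_KO mice did not overlap the 3 WT mice, where chance gives 10%. The count of calls was 3 with the muscle miRNA mean as a covariate, 8 without the 3 libraries with the most muscle miRNA and 0 with the number of miRNAs at the lowest value as a covariate. It was 3 without WT replicate 1, 7 without WT replicate 2, 6 without Hete_KO replicate 3, 2 without Homo_KO replicate 1, 3 without Homo_KO replicate 2 and 2 without Homo_KO replicate 3, and 25 without Hete_KO replicate 2.

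**Figure D2:**
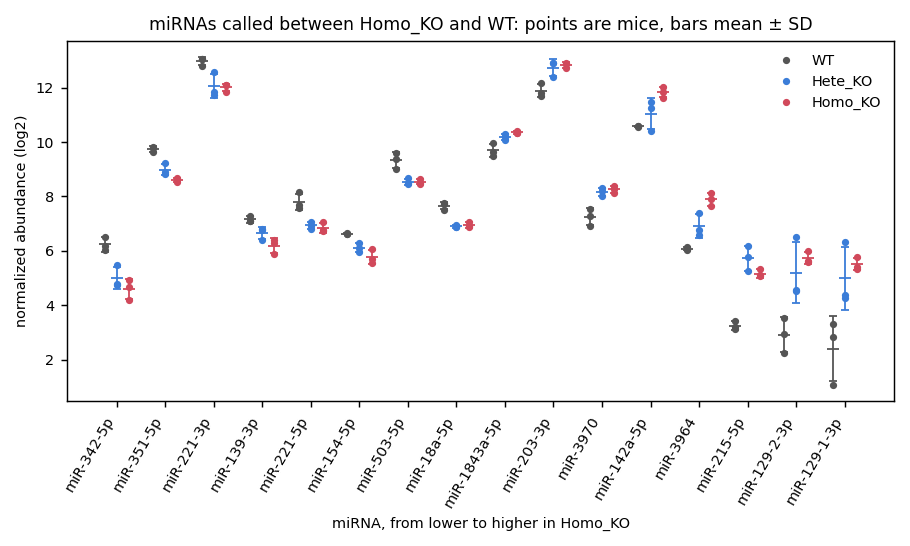
Normalized abundance (log2, vertical axis) of the 16 miRNAs called between Homo_KO and WT (horizontal axis, ordered by log2 fold change), with points for single mice and bars for mean ± SD of 3 mice in WT (grey), Hete_KO (blue) and Homo_KO (red). miR-142a-5p is near 10.57 in the WT mice, and between 11.63 and 12.02 in the Homo_KO mice.

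By miRNA list, the imprinted Dlk1-Dio3 cluster on chromosome 12, which is transcribed from the maternal chromosome, was lower in Homo_KO. All 52 tested members had negative log2 fold changes, with a median of -0.47 (camera, adjusted p = 1.46e-12, and adjusted p = 0.303 with an estimated correlation). Fry did not call it (adjusted p = 0.102), and with the depth covariate the median was -0.22, with 44 of 52 negative. Of these members 1 was called over all miRNAs and 6 were lower when adjusted over the list alone, among them miR-154-5p. Its most abundant members did not pass, with -0.19 ± 0.32 for miR-379-5p and -0.21 ± 0.18 for miR-411-5p (SE). The miR-30 family, which is abundant in adipocytes, was higher, with 10 of 11 members positive and a median of 0.44 (camera, adjusted p = 0.000349, and adjusted p = 0.299 with an estimated correlation). No miR-30 member was called over all miRNAs and 7 were higher when adjusted over the list alone. miR-30a-5p had a log2 fold change of 0.25 ± 0.09 and miR-30d-5p of -0.03 ± 0.08 (SE).

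The list for endothelium and angiogenesis was lower, with 29 of 46 members negative and a median of -0.29 (camera, adjusted p = 0.00131, and adjusted p = 0.299 with an estimated correlation). In this list 4 members were called, all lower: miR-221-3p, miR-221-5p, miR-503-5p and miR-18a-5p. Adjusted over the list alone, 8 were lower and 1, miR-130a-3p, was higher, the latter named after its value was seen. miR-126a-3p, the miRNA most typical of endothelium, was not called (-0.27 ± 0.19, adjusted p = 0.428), nor was miR-126a-5p (-0.47 ± 0.14, adjusted p = 0.0869), and of these arms 1 passed when adjusted over that list of 2 alone. The hypoxia-responsive miR-210-3p was at 7.11 ± 0.15 in WT and 7.32 ± 0.45 in Homo_KO (SD, n = 3 each), and miR-10b-5p had a log2 fold change of 0.13 ± 0.12. The call of this list ended without the 3 libraries with the most muscle miRNA (adjusted p = 0.0593).

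miRNAs reported to promote brown or beige adipocytes were higher as a list, with 23 of 28 positive and a median of 0.42 (camera, adjusted p = 0.000349, and adjusted p = 0.303 with an estimated correlation). The 3 called members were miR-129-1-3p and miR-129-2-3p, both under the filter's level in WT, and miR-203-3p. Adjusted over the list alone, 5 were higher. Of its abundant members, miR-26a-5p had a log2 fold change of 0.34 ± 0.12 and miR-26b-5p of 0.31 ± 0.14 (SE), without passing the test. miR-203-3p is also a skin and epithelial miRNA. The call ended with the stricter filter on low values (adjusted p = 0.0584) and with the depth covariate (adjusted p = 0.0981). miRNAs reported to inhibit brown or beige adipocytes had a median of 0.10 and a mean of -0.53, because the muscle miRNAs in that list lay far below the rest, and were not called (adjusted p = 0.795). Its most abundant members were miR-125b-5p (0.20 ± 0.23) and miR-27a-3p (0.18 ± 0.16).

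The other lists did not pass in Homo_KO against WT. The median log2 fold change was 0.11 for adipogenesis and obesity (camera, adjusted p = 0.747, with 2 called members, both arms of miR-221, and with 2 higher and 3 lower when adjusted over the list alone), 0.15 for the let-7 family (adjusted p = 0.133) and -0.16 for miR-17-92 and its paralogous clusters (adjusted p = 0.223, with miR-18a-5p called and 1 lower when adjusted over the list alone). Skeletal muscle had a median of -3.33 (adjusted p = 0.138), with miR-1a-3p at -3.33 ± 2.14 and miR-133a-3p at -3.76 ± 2.23 (SE). The medians were 0.18 for leukocytes (adjusted p = 0.795), where miR-142a-5p rose and miR-342-5p fell (2 higher and 1 lower when adjusted over the list alone), -0.54 for erythroid cells (adjusted p = 0.143) and 0.64 for epithelium and mammary gland (adjusted p = 0.111, with miR-203-3p called and 1 higher when adjusted over the list alone). They were -0.01 for fibroblast and mural cells (adjusted p = 0.951), 0.48 for neural miRNAs (adjusted p = 0.552) and -0.03 for liver (adjusted p = 0.795), and in fibroblast and mural cells and in liver the mean was positive. Leukocyte miRNAs averaged 12.15 ± 0.17 in WT and 12.53 ± 0.18 in Homo_KO (SD, n = 3 each, exact permutation test, two-sided p = 0.1, the smallest possible). Among the most abundant members of these lists, miR-150-5p had a log2 fold change of 0.71 ± 0.22, miR-146a-5p of 0.24 ± 0.21, miR-451a of -0.53 ± 0.27, miR-486a-5p of -0.56 ± 0.48, miR-182-5p of 0.17 ± 0.20, miR-338-3p of 0.69 ± 0.25 and miR-122-5p of 0.60 ± 1.72 (SE), and none was called. Further abundant members without a call were let-7a-5p (-0.19 ± 0.17), let-7f-5p (0.23 ± 0.13), miR-93-5p (0.10 ± 0.14), miR-25-3p (0.05 ± 0.11), miR-143-3p (0.19 ± 0.19), miR-21a-5p (-0.20 ± 0.22), miR-9-5p (0.53 ± 0.34) and miR-192-5p (-0.30 ± 0.65).

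**Figure D3:**
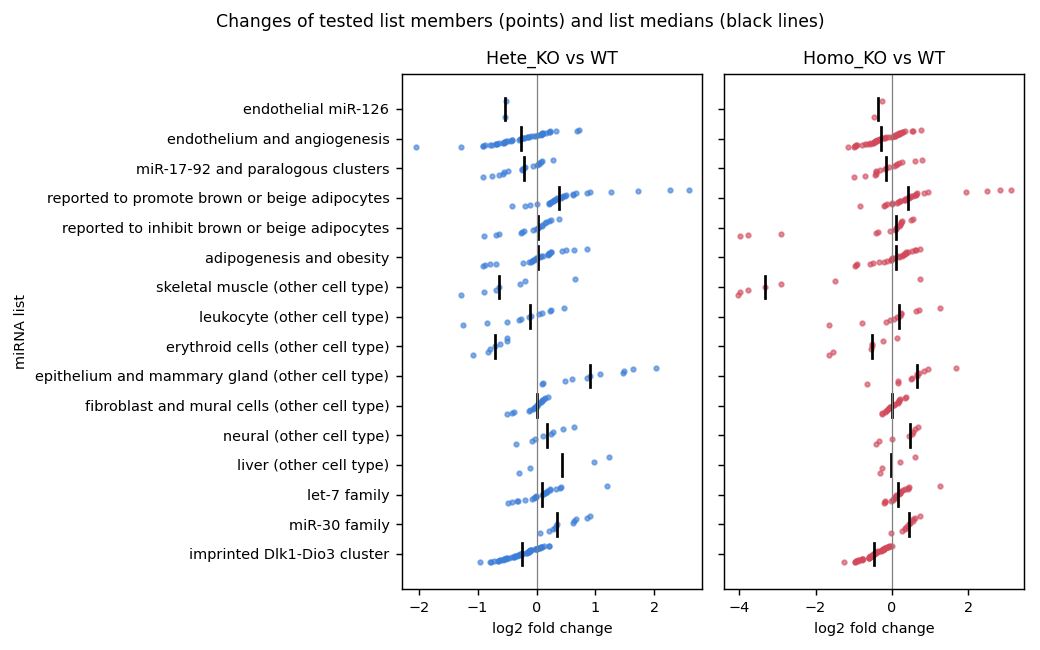
Log2 fold change (horizontal axis, with a wider range on the right) of each tested member (points) of the 16 miRNA lists (vertical axis), with list medians as black lines, for Hete_KO against WT (left, blue) and Homo_KO against WT (right, red). The 52 Dlk1-Dio3 members all lie below 0 on the right, and 11 of 11 miR-30 members lie above 0 on the left and 10 of 11 on the right.

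Hete_KO was compared with WT to ask what the other knockout genotype shows. Here 2 miRNAs passed the test, both higher. miR-215-5p rose 5.60-fold, from 3.25 ± 0.17 in WT to 5.74 ± 0.46 (SD, n = 3 each), a log2 fold change of 2.49 ± 0.28 (SE, limma, adjusted p = 0.00339). The WT mean of this miRNA is under the filter's level. miR-30e-3p rose 1.88-fold, from 11.92 ± 0.06 to 12.83 ± 0.12, a log2 fold change of 0.91 ± 0.15 (adjusted p = 0.0316). Its hairpin Mir30e lies on chromosome 4, 120772606 to 120772697, in an intron of Nfyc. The call of miR-30e-3p ended without WT replicate 1 (adjusted p = 0.201), WT replicate 2 (0.0583), Hete_KO replicate 2 (0.0673), Hete_KO replicate 3 (0.12) or Homo_KO replicate 3 (0.0898). With scaling by the median instead there were 4 higher and 2 lower miRNAs. At an unadjusted p under 0.05 there were 77 miRNAs, and 84 of the 489 (17.2%) had groups without overlap, where chance gives 10%.

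With so few calls, the miRNAs with the smallest p in Hete_KO are given as values. The higher side held miR-3970 (0.93 ± 0.18), miR-203-3p (0.85 ± 0.18) and miR-30a-3p (0.64 ± 0.14). On the lower side were miR-18a-5p (-0.76 ± 0.14), miR-351-5p (-0.75 ± 0.14), miR-221-5p (-0.87 ± 0.19), miR-20a-5p (-0.63 ± 0.13) and miR-503-5p (-0.79 ± 0.17), all SE, with limma adjusted p between 0.0548 and 0.0655 for these 8. The count of calls was 24 without Hete_KO replicate 1 and 12 without WT replicate 3, and 1 without WT replicate 1, without Hete_KO replicate 2, without Hete_KO replicate 3 or without Homo_KO replicate 3. It was 0 with the depth covariate.

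In Hete_KO, 7 lists passed camera, and none of them with an estimated correlation. The miR-30 family was higher, with 11 of 11 positive and a median of 0.34 (adjusted p = 7.06e-07, and adjusted p = 0.133 with an estimated correlation), with miR-30e-3p called and 6 higher when adjusted over the list alone. miRNAs reported to promote brown or beige adipocytes were higher, with 25 of 28 positive and a median of 0.38 (adjusted p = 8.29e-07, and adjusted p = 0.148 with an estimated correlation), with none called and 4 higher when adjusted over the list alone. Endothelium and angiogenesis was lower, with 32 of 46 negative and a median of -0.26 (adjusted p = 0.000163, and adjusted p = 0.133 with an estimated correlation), with none called, and 7 lower and 1 higher when adjusted over the list alone. In it miR-126a-3p was at -0.51 ± 0.19 and miR-126a-5p at -0.54 ± 0.14 (SE, limma, adjusted p = 0.221 and 0.0825), and both passed when adjusted over that list of 2 alone. The Dlk1-Dio3 cluster was lower, with 42 of 52 negative and a median of -0.25 (adjusted p = 0.000163, and adjusted p = 0.719 with an estimated correlation), with none called and none when adjusted over the list alone. That call of the list ended without Hete_KO replicate 3 (adjusted p = 0.0511), without the 3 libraries with the most muscle miRNA (adjusted p = 0.127) and with the depth covariate (adjusted p = 0.0855).

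Epithelium and mammary gland was higher in Hete_KO, with 11 of 11 positive and a median of 0.91 (adjusted p = 0.000267, and adjusted p = 0.187 with an estimated correlation), and Hete_KO replicate 1 held much of this difference. The mean of 3 epithelial miRNAs was 8.25 there and 4.97 and 4.06 in the other Hete_KO mice, against 4.42 to 4.71 in WT, and without that replicate the list's median was 0.50, with 10 of 11 positive (adjusted p = 0.00757). Its call ended without the 3 libraries with the most muscle miRNA (adjusted p = 0.102). miR-17-92 and its paralogous clusters, which promote proliferation, were lower with a median of -0.22 (adjusted p = 0.0225, and adjusted p = 0.472 with an estimated correlation), a call that ended without WT replicate 1 (adjusted p = 0.099) or Hete_KO replicate 1 (adjusted p = 0.149). Erythroid miRNAs were lower with 7 of 7 negative and a median of -0.70 (adjusted p = 0.0323, and adjusted p = 0.719 with an estimated correlation), a call that ended without WT replicate 1, WT replicate 2, Hete_KO replicate 1 or Hete_KO replicate 3 (adjusted p from 0.106 to 0.622). These 7 are not independent (estimated correlation 0.803), and both arms of miR-486a and of miR-486b are among them. Adjusted over each list alone, 1 epithelial miRNA was higher, and 2 of miR-17-92 and its paralogous clusters and 1 erythroid miRNA were lower. Among the lists that did not pass, this gave 2 higher and 2 lower for adipogenesis and obesity and 1 lower for leukocytes. miR-451a, of red blood cells, was at -1.09 ± 0.27 (SE, limma, adjusted p = 0.0825). The 8 lists that did not pass had medians of 0.02 for miRNAs reported to inhibit brown or beige adipocytes, 0.03 for adipogenesis and obesity, -0.63 for skeletal muscle, -0.11 for leukocytes, 0 for fibroblast and mural cells, 0.18 for neural miRNAs, 0.43 for liver and 0.10 for the let-7 family, with adjusted p from 0.412 to 0.969. The mean was negative for miRNAs reported to inhibit brown or beige adipocytes (-0.10) and for fibroblast and mural cells (-0.04), and camera's direction for the former was up.

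Homo_KO and Hete_KO were compared directly to see whether the knockout genotypes differ. No miRNA passed limma's test (0 of 489, smallest adjusted p = 0.509), and 41 had an unadjusted p under 0.05. In 12.3% of miRNAs the groups did not overlap, where chance gives 10%. The smallest p values on the higher side in Homo_KO were those of miR-3964 (0.98 ± 0.23), miR-34c-5p (0.87 ± 0.25), miR-466b-3p (0.59 ± 0.18) and miR-467a-5p (0.999 ± 0.286). Values of miR-467a-5p are identical to those of miR-467b-5p in every library, and those of miR-466b-3p to those of miR-466c-3p and miR-466p-3p. On the lower side they were those of miR-3068-3p (-0.52 ± 0.19), miR-351-5p (-0.38 ± 0.14), miR-30e-3p (-0.35 ± 0.15), miR-139-3p (-0.46 ± 0.19) and miR-1193-3p (-0.77 ± 0.33), all SE. The Dlk1-Dio3 cluster was lower in Homo_KO than in Hete_KO, with 43 of 52 negative and a median of -0.19 (camera, adjusted p = 9.15e-08, and adjusted p = 0.904 with an estimated correlation). That call ended without Hete_KO replicate 1 (adjusted p = 0.114) or Homo_KO replicate 2 (adjusted p = 0.112). The other 14 lists did not pass, with adjusted p from 0.0526 for skeletal muscle (median -2.75) to 0.953 for miRNAs reported to inhibit brown or beige adipocytes. Median, mean and camera's direction differed in sign for miRNAs reported to promote (median 0.01, direction down) and to inhibit brown or beige adipocytes (median 0.02, mean -0.43), adipogenesis and obesity (median 0.04, direction down) and erythroid cells (median -0.04, mean 0.02). No list member was called, also when adjusted over a list alone. Without the 3 libraries with the most muscle miRNA, 4 miRNAs were called.

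The 3-genotype test called 6 miRNAs (limma F-test, adjusted p under 0.05, with 92 at an unadjusted p under 0.05): miR-215-5p (adjusted p = 0.0086), miR-3964 and miR-351-5p (adjusted p = 0.0118 each), miR-30e-3p and miR-3970 (adjusted p = 0.0472 each) and miR-18a-5p (adjusted p = 0.0474). Of these, 5 were also called in Homo_KO against WT. The count was 0 without WT replicate 1, 3 without WT replicate 2, 17 without Hete_KO replicate 1, 11 without Hete_KO replicate 2, 3 without Hete_KO replicate 3, 3 without Homo_KO replicate 1, 1 without Homo_KO replicate 2, 1 without Homo_KO replicate 3 and 0 with the depth covariate.

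The changes in both knockouts were set against each other across the 489 miRNAs, which are not independent replicates. The log2 fold changes against WT had a Pearson correlation of 0.718 and the same sign in 75.9% of miRNAs. Because both use the same 3 WT mice, 100 simulations redrew all libraries from the spread within groups, with no group effect. In each, both knockouts were compared with the same redrawn WT group. The simulations gave a mean correlation of 0.460 (SD 0.443, highest 0.979) and the same sign in 67.4%. The covariance was 0.236, against a mean of 0.102 in the simulations, a difference of 0.134, and the highest simulated covariance was 0.763, so the observed value lies within the simulated range. In the calls, 1 miRNA was higher in both, miR-215-5p, and none was lower in both. Independent lists would share 0.0327 higher miRNAs, a value that leaves out the shared WT mice, and the simulated groups shared a mean of 0.02 higher and 0.39 lower calls (highest 2 and 34). The WT group is too small to split, so part of what both knockouts share may come from the shared mice.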

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

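The muscle and depth covariates, the fit without the 3 libraries with the most muscle miRNA, and every value for both knockouts together were chosen after the data were seen. Of 2828 values of named miRNAs under the alternatives, 2651 stayed on the same side of the threshold, 105 lost and 70 gained a call, and 2 reversed. All 303 values of called miRNAs kept their sign, and 120 values of uncalled ones changed it, the 2 reversals among them. Both reversals came without the 3 libraries with the most muscle miRNA, which leaves a single WT mouse assumed to vary like the others: let-7c-5p (-0.18) and let-7b-5p (-0.38) in Homo_KO, where abundant miRNAs share rank levels and the spread is close to 0 (SE 0.00473 and 0.00696). For the other shifts the cause was not tested, except where fewer or more miRNAs were tested and for the 16 calls in Homo_KO with a covariate, whose SE grew.

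Counts of calls in Homo_KO against WT (16) were 9 without a filter (860 tested), 25 with the stricter filter (262 tested), 74 with sample weights, 3 with the muscle covariate, 8 without the muscle-rich libraries and 0 with the depth covariate, and ran from 2 to 25 with a library left out. In Hete_KO against WT (2) they were 10 with the stricter filter, 6 with median scaling, 1 without a variance trend, 34 with sample weights, 1 with only the groups compared, 10 without the muscle-rich libraries and 0 with the depth covariate, and from 1 to 24 with a library left out. Homo_KO against Hete_KO gave 4 without the muscle-rich libraries and 0 otherwise. The 3-genotype test (6) gave 16 with the stricter filter, 3 without a trend, 52 with weights, 11 without the muscle-rich libraries, 0 with the depth covariate and 0 to 17 with a library left out. Both knockouts together (41) gave 27 without a trend, 88 with weights, 16 with the muscle covariate, 9 without the muscle-rich libraries, 0 with the depth covariate and 1 to 49 with a library left out.

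Lists called in Homo_KO against WT (4) were 0 with an estimated correlation, 3 with fry, which did not call the Dlk1-Dio3 cluster (adjusted p = 0.102), 7 with the depth covariate and 4 to 8 with a library left out. In Hete_KO against WT (7) they were 0 with an estimated correlation, 2 with fry and 5 to 7 with a library left out. In Homo_KO against Hete_KO (1) they were 0 with an estimated correlation and with fry, 2 with a pseudocount of 0.1, with only the groups compared, with either covariate and without the muscle-rich libraries, 3 with the stricter filter and 0 to 3 with a library left out. The correlation of the changes stayed between 0.507 and 0.887. A pseudocount of 1 is the scale of the deposited values and was not run again.

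The mice share only a replicate number, with no pairing in the labels: of 9 pairs with the same number 5 had correlated deviations over 0.1 (from -0.282 to 0.548). As a hint of pairing from the data, not the design, 7 of 9 libraries correlated best with one of their own number. The hint is weak, since pairs with different numbers ran from -0.702 to 0.539, nearly as high as those with the same number. With the replicate number as a block the calls were 25 in Homo_KO, 15 in Hete_KO and 16 in the 3-genotype test, and 2 lists in Homo_KO against Hete_KO.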

Other observations

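The tests of clusters, muscle tissue, depth, endothelial share, chromosomes 4 and X and both knockouts together were chosen after the results were seen, as were the bounds for the regroupings of mice, and the bound for endothelial share was set again after its first outcome. Grouping tested hairpins of the same strand within 10 kb gave 34 clusters of at least 3 miRNAs, and 4 were lower in Homo_KO than in WT (camera, none with an estimated correlation). Of these, 2 were the parts of the Dlk1-Dio3 region, from Mir673 to Mir136 (median -0.57, 13 of 13 negative) and from Mir379 to Mir410 (median -0.43, 39 of 39 negative). The other clusters lie on chromosome X: Mir221 and Mir222 (GRCm38 19146294 to 19146971, median -0.93, 4 of 4 negative, adjusted p = 0.00213) and Mir450b to Mir322 (53047997 to 53054349, median -0.51, 8 of 9 negative, adjusted p = 0.000441). In Hete_KO 9 clusters were called (camera, none with an estimated correlation), among them the same X-linked clusters with medians of -0.78 and -0.41 (adjusted p = 0.013 and 0.00483, and 0.659 and 0.368 with an estimated correlation). The others were both Dlk1-Dio3 parts (-0.36 and -0.16), Mir144 to Mir451a (-0.70), Mir17 to Mir20a (-0.52) and Mir296 to Mir298 (-1.30), and on the higher side Mir30b to Mir30d (0.475) and Mir30c-1 to Mir30e (0.34). Sex is not given in the labels used here. A shift of the whole X chromosome as the source of these clusters was tested on the other 32 X-linked miRNAs in Homo_KO. Their median was 0.131 (quartiles -0.192 and 0.456), against -0.533 in the 13 miRNAs of the clusters. The clusters were picked for being lower, so this gap is partly built in. Leaving out these clusters also raised the median of the other miRNAs. Of those others 20 were positive and 12 negative, beside 4 of 4 and 8 of 9 negative in the clusters. X-linked miRNAs thus went both ways, which speaks only weakly against a uniform shift of the chromosome. A difference in sex was not tested.

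With both knockouts in a single group, 41 miRNAs differed from WT, 22 higher and 19 lower (limma, adjusted p under 0.05), and these included the 16 called in Homo_KO. The count was 1 without WT replicate 1, 4 without Homo_KO replicate 3, 9 without the 3 libraries with the most muscle miRNA and 0 with the depth covariate. Outside those 16 they include miR-30a-3p (0.62), miR-130a-3p (0.72) and miR-132-3p (-0.68), named after their values were seen. miR-30f, which is antisense to Mir30e on chromosome 4 and lay under the filter, was the only untested miRNA at the lowest value in all 3 WT libraries and above it in all 6 knockouts (1.48 to 1.87), and no miRNA showed the opposite. Mir30e lies on the same chromosome as Ago1 (126435012 to 126468583), so sequence carried along with the Ago1 allele could change miR-30 miRNAs. Of all tested miRNAs of chromosome 4, 16 of 20 were positive with a median of 0.338 (camera p = 0.0106, and p = 0.0315 with an estimated correlation), but these hold the miR-30 arms that raised the question and the epithelial cluster from Mir429 to Mir200b. Without both, 13 were left, with 9 positive and a median of 0.127 (camera p = 0.363 and p = 0.484 with an estimated correlation), which does not settle it. Against that for the family, the 7 arms from other chromosomes were all positive with a median of 0.554, though miR-30d-5p was only at 0.016. Camera gave p = 0.000123, and p = 0.0441 with an estimated correlation. These arms belong to a list already called higher in the same mice, so the p is not independent evidence of a rise. Left out was miR-30c-5p, which has copies on chromosome 4 and elsewhere. For the 3 arms from chromosome 4, with a median of 0.392, the explanation cannot be told apart from a change shared by the family.

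The first pattern weighed was the set of 16 miRNAs in Homo_KO. Of the 10 splits of the 6 mice, 1 gave as many calls, the real one, with 2 in the highest other, and 10 splits are too few for a share under 0.05. With the muscle covariate their log2 fold changes kept most of their size, with a median ratio to those without it of 0.957 (quartiles 0.905 and 1.02). This speaks against muscle tissue as the main source of these 16. But a call needs a small spread within groups, and muscle miRNAs varied widely there. Called miRNAs were thus unlikely to follow muscle, and the ratio had little room to fall. The depth covariate gave a ratio of 0.939 (quartiles 0.857 and 1.06). But it is only a coarse trace of depth and correlates with knockout at 0.703. Depth therefore cannot be told apart from the genotype for these calls. Both covariates ended calls (3 and 0 left): the median SE rose from 0.190 to 0.232 and 0.254, while the median size went from 0.992 to 0.939 and 0.961. The endothelial knockout stays open as a biological explanation, and a litter or cage shared within a genotype was not tested.

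Regrouping the mice gave these counts elsewhere. In Hete_KO against WT, 2 of the 10 splits gave as many miRNAs as the real one (2, with 3 in the highest other), and in Homo_KO against Hete_KO all 10 did (0, with 0 in the highest other). For lists, as many as the real number came in 4 of 10 splits for Homo_KO against WT (4, with 5 in the highest other, WT replicates 1 and 2 with Homo_KO replicate 1 against the rest, the 3 of these 6 with the most muscle miRNA), 1 of 10 for Hete_KO against WT (7, with 5) and 10 of 10 for Homo_KO against Hete_KO (1, with 4). None of these splits is numerous enough for a share under 0.05. Chance is a less likely source for the 3-genotype test, where 1 of 100 partitions gave as many (6, with 4 in the highest other). That was the real partition, which was always among the 100. For both knockouts against WT, 1 of 84 splits gave as many (38 in a fit of 2 groups, with 7 in the highest other). This comparison was chosen after the data were seen. Without WT replicate 1 the limma calls were 0 in the 3-genotype test and 1 for both knockouts, so chance is not excluded. Regrouping the mice does not test depth or muscle tissue, and so excludes neither as a source of the calls in these tests. In the other lists called, the medians with the muscle and depth covariates were -0.262 and -0.186 for endothelium and angiogenesis, 0.441 and 0.463 for the miR-30 family and 0.379 and 0.419 for miRNAs reported to promote brown or beige adipocytes.

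The second pattern was the lower Dlk1-Dio3 cluster in Homo_KO. Muscle tissue as the cause is argued against, since the median with the muscle covariate was -0.427 (49 of 52 negative, camera adjusted p = 1.65e-08) against -0.475 without it. Library depth cannot be told apart from the genotype here: with the depth covariate, which correlates with knockout at 0.703, the median was -0.22, with 44 of 52 negative (camera adjusted p = 6.07e-06). The abundant 26 members moved as much as the others, from -0.469 to -0.229. An estimated correlation ends the call in any case, so that the cluster may behave as a single unit across few mice.

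The third pattern was the lower miRNAs of the endothelium and angiogenesis list in Homo_KO. A smaller share of endothelial cells could lower them, and would lower miR-126a by at least as much. The mean of both miR-126a arms was -0.366, against a median of -0.87 in the 4 called members, but the intervals overlap (-0.738 to -0.193 for miR-126a-5p, -0.646 to 0.113 for the more abundant miR-126a-3p, and up to -0.433 for the called members at 2 SE), so the explanation cannot be told apart from a change within cells. In both knockouts together miR-126a-5p was called lower (-0.50, limma, adjusted p = 0.037) and miR-126a-3p was not (-0.39, adjusted p = 0.197).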
